A study of Mus musculus with 31 samples.

How the data were processed

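The series held 31 samples of mouse oocytes and embryos in 16 groups: 20 whole-genome bisulfite samples, 8 RNA-seq samples and 3 ChIP-seq samples. The ChIP-seq samples were not analysed here. Groups were taken from the labels. Oocytes came from females with or without a conditional knockout (cKO) of G9a, the H3K9 methyltransferase encoded by Ehmt2, and embryos came from control or cKO oocytes (maternal KO). The 2-cell embryos had JF1 fathers, and their deposited bisulfite files hold the reads assigned to the maternal allele, per the labels.

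Per the labels, bisulfite libraries were made by post-bisulfite adaptor tagging, in which adaptors are added after conversion, and unmethylated lambda DNA was spiked in. The lambda reads were not used here, so the conversion rate of each library is not known from the files. For each CG position the deposited files give counts of methylated and unmethylated reads, and the authors pooled the 2 samples of each group into 1 file. The 10 pooled files carry no spread between samples. A read that spans several CG positions enters each of them, and reads have no molecular identifiers, so intervals from these counts cover counting error only. RNA values are FPKM per gene in the authors' deposited tables, 1 table per stage, with library names in the columns. Per the labels, RNA was depleted of ribosomal RNA and the kit kept strand, and libraries were run on several instrument models without a record of which library went on which, so a batch of this kind could not be tested. Whether strand was used for the values is not given in the sources used here, so genes that overlap on opposite strands are uncertain. Per the submitters' processing notes the tools were Bowtie2 2.2.9, Picard 2.6.0, Trim Galore 0.3.3, Bismark 0.14.5, HISAT2 2.0.5 and StringTie 1.3.3 on the mouse build mm10 (GRCm38); which tool served which assay, and with which settings, is not given in the sources used here. FPKM assigned to near-identical copies of a gene is uncertain, since how shared reads were divided is not stated. Coordinates are those of the deposited tables, 1-based.

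FPKM hold no read totals. Among 1754 genes under 0.5 FPKM in the FGO table, the commonest ratio of a library to control replicate 1 was shared by at most 88 genes, so relative depth could not be read from the values. Genes with FPKM of at least 1 in at least 2 of the 4 libraries of a stage were kept. Values were tested as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (eBayes with trend), with Benjamini-Hochberg adjustment and a threshold of 0.05; p-values are 2-sided except for overlaps of calls, where Fisher's exact test was one-sided. A log2 change on this scale understates the change of genes with low values. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. The change between stages was tested as an interaction over all 8 libraries. Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. There were 18 lists: H3K9 methylation machinery, DNA methylation machinery, oocyte-specific genes, meiotic genes, germline genes silenced by methylation in somatic cells, 2-cell activation genes, maternal mRNA decay factors, imprinted genes, granulosa and theca cell markers, blood and immune markers, sperm and testis transcripts, p53 targets, inner cell mass and trophectoderm regulators, heat shock and stress genes, ribosomal protein genes, nuclear-encoded oxidative phosphorylation genes, mitochondrial-encoded genes and replication-dependent histone genes. The mitochondrial-encoded list had 0 kept members in either table.

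Methylation levels are methylated reads over all reads at CG positions covered in both files of a stage. The global level is over the 19 autosomes, with a 95% interval from 1000 bootstrap draws of 1 Mb blocks, which covers variation along the genome and not between animals. Levels were computed in 10 kb windows with at least 10 shared positions and 50 reads in each file. Fisher's exact test was run per window, and a window was called at an adjusted p under 0.05 and a difference of at least 20 percentage points. Every Fisher test here compares the 2 pooled files, not the conditions. No gene strand was used, so promoters could not be placed. In their place the CG-richer end of each gene, plus or minus 1 kb, was taken, and the gene body was the span without 1 kb at each end; both needed 5 positions and 20 reads per file and had the same thresholds. Windows were classed as low (under 20%), middle or high (over 80%) by another control file, so that the class was not set by the values compared. The imprinted regions were 22 gene ends or intervals upstream of H19 (4 to 2 kb), Meg3 (14 to 12 kb) and Rasgrf1 (31 to 29 kb).

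Read depth of the pooled files was compared in 1 kb bins, leaving out positions over 200 reads, after scaling to the files' totals and adding 1 read. Bins with at least 200 reads in the file with more and a 4-fold or larger ratio were joined into stretches. This comparison was chosen after the data were seen.

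Groups, tests, thresholds, lists, named genes and most alternatives were fixed before the data were examined. Named were Ehmt2, the 10 largest rises and 10 largest falls among genes past the threshold with groups that did not overlap and FPKM of at least 1 throughout the higher group, up to 4 members of each list with the smallest p, and the 3 largest falls and 3 largest rises among called windows with at least 100 reads per file. With fewer than 5 genes past the threshold in a direction, the 5 with the smallest p were named as not passing. Of those lower in 2-cell embryos, 2 are not reported here. The overlap of gene body and RNA calls and the read-depth comparison were added after the data were seen. The RNA simulation's noise model was changed after its first output.

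The RNA steps were tested on simulated data with 200 changed genes. In FGO the test called 27 of 50 genes changed by 1 on the log2 scale, 41 of 50 at 2, 48 of 50 at 3 and 48 of 50 at 4, with 14 of 10750 unchanged genes called. In 2-cell embryos it called 0, 0, 7 and 26 of 50, with 1 of 11883 unchanged genes. With FGO read depths, the window test called 0, 30, 49 and 49 of 50 windows lowered by 10, 20, 30 and 40 points, and 1 of 19800 unchanged windows. The simulated reads were independent, whereas real reads can enter several CG positions and come from 2 pooled samples. These window counts therefore do not give the rate of false calls in the real files.

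Alternatives tried were pseudocounts of 0.1 and 1, other FPKM filters, other scalings, the replicate number as a block, eBayes without trend or robust, an adjusted p threshold of 0.1, all 8 libraries in 1 model and each library left out. For methylation they were other coverage minimums, 2 kb windows, thresholds of 10 and 30 points, centred differences, thinning to equal reads, all positions of each file, and leaving out positions over 200 reads. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.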

Results

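DNA methylation and RNA were measured in mouse oocytes and embryos without the maternal supply of G9a, the enzyme encoded by Ehmt2 that places mono- and dimethylation on lysine 9 of histone H3, a mark of silent chromatin. Whole-genome bisulfite sequencing covered 5 stages: growing oocytes (GO) from ovaries at postnatal day 10, fully grown oocytes (FGO), metaphase II oocytes (MII), 2-cell embryos (reads of the maternal allele) and blastocysts 120 hours after fertilization. Per the labels, all stages but GO came from females at least 10 weeks old, so GO differ from the later stages in the age of the females too. Each stage had a control and a knockout group of 2 samples, deposited as 1 pooled file per group, so methylation values have no spread between samples. RNA-seq covered FGO and 2-cell embryos 24 hours after fertilization, with 2 control and 2 knockout libraries each.

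The pooled files held between 15790749 reads at CG positions (MII control) and 162274272 (blastocyst maternal KO). The mean reads per covered position ran from 2.25 in the MII cKO file to 4.71 in the blastocyst maternal KO file. FGO files held 4.63 (control) and 4.51 (cKO) reads per position over 32712399 and 32693532 positions, while the MII control file covered 4909514 positions and the 2-cell files 5788263 and 5993903. Positions with over 200 reads, few in number, took between 10.8% (MII cKO) and 24.4% (2-cell control) of the reads. The RNA tables give FPKM and not read totals, so the depth of the RNA libraries is unknown. Genes with FPKM of at least 1 numbered 10607 and 10707 in the FGO controls, 10727 and 10950 in the FGO cKO, 11267 and 11763 in the 2-cell controls and 11183 and 12053 in the 2-cell maternal KO. Replicates correlated at r = 0.980 (control) and 0.976 (cKO) in FGO and at 0.863 and 0.894 in 2-cell embryos, where correlations between libraries of different groups ran from 0.837 to 0.945.

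Ehmt2 RNA (chromosome 17, 34898492 to 34914050) was not lower in FGO: its FPKM was 3.14 and 3.91 in controls and 3.99 and 4.63 in cKO (log2 difference 0.26, SE 0.16, limma adjusted p = 0.370). In 2-cell embryos it was 6.35 and 4.36 in controls and 0.862 and 3.81 in maternal KO (log2 difference -1.25, SE 0.69, limma adjusted p = 1.00). FPKM of a whole gene does not separate a deleted part from the rest, so these values do not check the labels, which do not say which part was removed. In the pooled bisulfite files, the 1 kb bin from 34912001 to 34913000 of Ehmt2 held 134 reads in the FGO control and 43 in the FGO cKO file, a ratio of 0.335 after scaling to the files' totals. The rest of the gene held 2914 and 2886 reads (1.02). The scaled ratio of that bin was 0.331 in blastocysts (118 and 43 reads) and 0.492 in GO (41 and 18), but 0.855 in MII (20 and 23), and the 2-cell files held only 2 and 12 reads. The bin was chosen after its values were seen, as the lowest of 16 bins of Ehmt2 in FGO.

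Stretches of DNA on chromosomes 5 and 8 were covered several times more deeply in the knockout files. On chromosome 5, positions 135974001 to 135980000, within Ssc4d and ending 105 bp before Zp3, which encodes an egg coat glycoprotein, held 335 reads in the FGO control and 6607 in the FGO cKO file, a scaled ratio of 20.2. The ratio was 13.98 in GO, 21.3 in MII, 8.14 in 2-cell embryos and 10.3 in blastocysts. On chromosome 8, positions 94179001 to 94181000, which hold Mt1, the gene of a metal-binding metallothionein, had 624 and 5018 reads in FGO, a ratio of 8.24, with 6.61 in GO, 6.40 in MII and 6.43 in blastocysts; neither 2-cell file had reads there. The sequence on either side of Mt1 had ratios of 0.795 to 1.06 in these stages. Among 11 stretches past 4-fold in FGO, 6 with more and 5 with fewer reads in cKO, these were the 2 that also passed 4-fold in GO, MII and blastocysts. The comparison was made after the data were seen, and a read that spans several CG positions is counted at each.

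**Figure D1:**
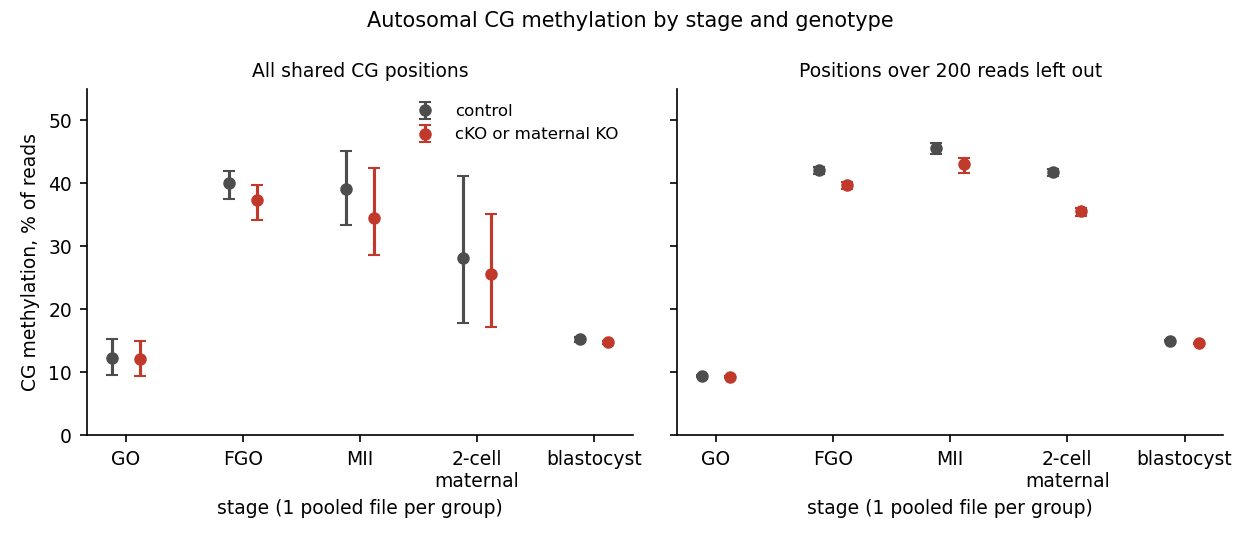
CG methylation (percent of reads, y axis) of control and knockout files at each stage (x axis), over all shared autosomal positions (left) and without positions over 200 reads (right); points are pooled files and bars are 95% bootstrap intervals over 1 Mb blocks. The knockout point lies below its control at all 5 stages in both panels, by -2.73 points in FGO and -0.465 in blastocysts on the left.

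The first comparison asked whether G9a affects DNA methylation while oocytes grow. In GO, a window at Slc4a7, a bicarbonate transporter gene (chromosome 14, 14740001 to 14750000), was 46.8% methylated in control and 11.7% in cKO, and a window at Emc2, a subunit of the membrane protein insertion complex (chromosome 15, 43480001 to 43490000), was 43.3% and 9.26%. In the other direction, windows at Snx13, a sorting nexin gene (chromosome 12, 35060001 to 35070000), and Fhit, a tumour suppressor gene (chromosome 14, 10130001 to 10140000), rose from 10.8% to 47.5% and from 8.93% to 42.3%. The largest differences outside genes were at chromosome 18, 40160001 to 40170000 (43.7% and 9.77%), and chromosome 13, 101430001 to 101440000 (10.7% and 43.9%). Each of these windows had over 100 reads per file. By Fisher's exact test, which compares the 2 pooled files, not the conditions, 1130 of 200966 windows were lower and 640 higher in cKO. The global level was 12.3% in control and 12.05% in cKO, a difference of -0.210 points (95% interval -0.292 to -0.116), lower on 15 of 19 autosomes. Windows that were over 80% methylated in MII controls stood at 18.6% in GO control and 16.9% in GO cKO, while windows under 20% in MII controls stood at 3.38% and 4.12%.

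In FGO, which have finished growing, large blocks changed in both directions. Within Zfp536, which encodes a zinc finger protein, the window at chromosome 7, 37560001 to 37570000, was 8.85% methylated in control (1560 reads) and 94.5% in cKO (1825 reads), and the one from 37580001 to 37590000 rose from 8.61% to 94.0%. A window outside any listed gene on chromosome 8, 30230001 to 30240000, went from 11.7% to 98.2%. The largest falls lay together on chromosome 15 outside listed genes, from 84.6% to 6.55% at 58560001 to 58570000, from 85.9% to 7.97% at 58610001 to 58620000 and from 88.3% to 10.3% at 58550001 to 58560000. The global level was 40.04% in control and 37.3% in cKO, a difference of -2.73 points (95% interval -3.26 to -2.29), lower on all 19 autosomes, and chromosome X stood at 44.3% and 40.5% (without positions over 200 reads).

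Of 251477 FGO windows, 7472 were lower and 5385 higher in cKO by Fisher's exact test on the pooled files. After centring on the median difference of all windows, which was -2.27 points, 5607 were lower and 6594 higher. As a background, the FGO and MII control files differed by the same thresholds in 3867 of 93867 windows (4.12%), with 770 lower and 3097 higher in MII. These files differ in stage and were run with different instrument software per the labels. The FGO cKO and control files differed in 3467 of the same 93867 windows (3.69%), with 2246 lower and 1221 higher in cKO. The cKO files of FGO and MII differed in 2916 of 122336 windows (2.38%), with 295 lower and 2621 higher in MII. Windows that were middle in MII controls averaged 42.3% in FGO control and 39.7% in FGO cKO, high windows 90.0% and 88.0%, and low windows 9.31% and 7.37%. Gene bodies were called lower in 517 genes and higher in 165 of 19955, with medians of 67.6% and 63.3%. CG-richer gene ends were lower in 371 and higher in 247 of 22258. Among genes with FPKM of 10 or more in FGO controls, 61 bodies were lower and 2 higher of 5926, with medians of 88.8% and 87.3%. Among genes under 0.1 FPKM, 134 were lower and 104 higher of 6912, with medians of 11.6% and 7.98%.

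In MII oocytes, which have matured, Plec, the gene of the cytoskeletal linker plectin, had the largest falls, from 92.2% to 17.9% at chromosome 15, 76180001 to 76190000, and from 97.0% to 26.7% at 76170001 to 76180000. A window of Prrc2b (chromosome 2, 32210001 to 32220000) fell from 89.5% to 47.8%. The first Zfp536 window rose from 4.38% (160 reads) to 79.8% (114 reads), and windows on chromosome 16, 3650001 to 3660000, and chromosome 5, 15500001 to 15510000, rose from 35.4% to 79.0% and from 14.3% to 53.9%. The global level was 39.2% in control and 34.4% in cKO, a difference of -4.72 points (95% interval -5.05 to -2.68). Without positions over 200 reads it was 45.6% and 43.0%, a difference of -2.56. By Fisher's exact test, 577 of 11412 windows were lower and 220 higher. Few windows could be tested, since the MII files shared 1740221 autosomal positions; with all positions of each file, 6203 of 96266 windows were lower and 3566 higher, a setting chosen after seeing the data.

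Differences seen in FGO recurred in MII. Of FGO windows called lower, 273 of 284 with MII data were lower there too (96.1%, against 53.1% of all windows), and of those called higher, 59 of 64 were higher (92.2%, against 38.9%). Calls overlapped in 182 lower windows, where 14.4 would follow from independent lists, and in 40 higher windows, where 1.23 would. Over 11412 windows the differences correlated at r = 0.539 and rho = 0.256; windows are not independent replicates. Differences in GO and FGO went together little: over 200964 windows r was 0.0147, and 25 windows were lower in both, where 25.8 would follow from independent lists, but 26 were higher in both, where 12.6 would. FGO windows called higher were higher in GO in 61.6% (against 51.5% of all windows) and those called lower were lower there in 48.9% (47.6%). GO windows called higher were higher in FGO in 40.8% (30.6%) and those called lower were lower there in 59.8% (69.4%).

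The next comparison asked whether these differences lasted on the maternal allele after fertilization. In 2-cell embryos the Plec window from 76180001 was again the largest fall, from 96.6% to 10.6%. Windows at Mab21l3 (chromosome 3, 101830001 to 101840000) and at chromosome 17, 27390001 to 27400000, fell from 81.7% to 3.92% and from 81.2% to 4.33%. The largest rises were in Slc14a2, a urea transporter gene (chromosome 18, 78340001 to 78350000; 18.97% to 94.5%), Gab1, which encodes an adaptor protein of growth factor receptors (chromosome 8, 80770001 to 80780000; 16.9% to 89.1%), and Klf12, a Kruppel-like transcriptional repressor gene (chromosome 14, 99870001 to 99880000; 16.2% to 87.1%). By Fisher's exact test, 7056 of 65319 windows were lower and 1691 higher in maternal KO. After centring on the median difference of -5.66 points, 3580 were lower and 2590 higher. Of FGO windows called lower, 1620 of 1688 were lower in 2-cell embryos (96.0%, against 71.2% of all windows), and of those called higher, 763 of 806 were higher (94.7%, against 28.4%).

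The global level on the 2-cell maternal allele was 28.2% in control and 25.7% in maternal KO, a difference of -2.51 points (95% interval -6.09 to -0.633), lower on 18 of 19 autosomes. Without positions over 200 reads it was 41.8% and 35.6%, a difference of -6.20, and at positions with at least 5 reads in both files it was 0.271, so the size and sign of this value differ with the weight given to deeply read positions. Sparsely methylated windows (under 20% in FGO control) averaged 13.96% in the 2-cell control and 5.49% in maternal KO. Windows over 80% in FGO control averaged 87.3% and 85.7%. Bodies of genes under 0.1 FPKM in FGO control had medians of 18.6% and 5.79%.

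In blastocysts, whose genomes have passed through embryonic demethylation, windows moved little. A window on chromosome X, 124210001 to 124220000, fell from 61.1% to 20.3%, one at Gm13769 and Olfr1506, an olfactory receptor gene (chromosome 2, 90240001 to 90250000), from 34.3% to 2.96%, and one at chromosome 7, 51120001 to 51130000, from 42.7% to 15.4%. Rises were led by chromosome X, 28770001 to 28780000 (36.7% to 68.5%), chromosome 16, 80760001 to 80770000 (25.6% to 57.4%), and chromosome 4, 96930001 to 96940000 (15.3% to 46.7%). By Fisher's exact test, 87 of 251396 windows were lower and 232 higher. The global level was 15.2% in control and 14.8% in maternal KO, a difference of -0.465 points (95% interval -0.616 to -0.328). Of the FGO windows called lower, 68.4% were lower in blastocysts (against 51.7% of all windows), with a median difference of -2.55 points. Of those called higher, 82.9% were higher (against 48.3%), with a median of 4.78 points. The blastocyst files hold both alleles, with 0.0951% (control) and 0.0697% (maternal KO) of reads on chromosome Y.

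**Figure D2:**
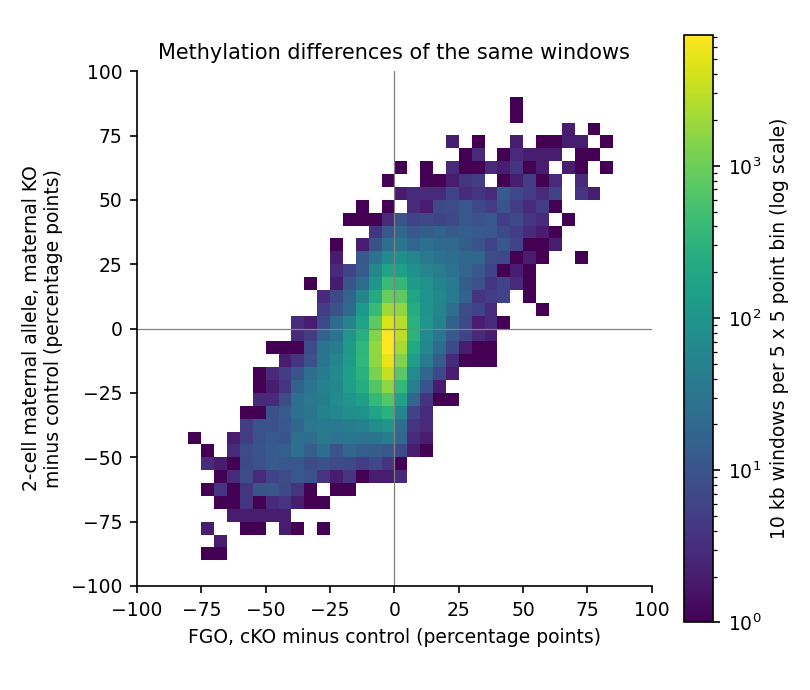
Difference of methylation (knockout minus control, percentage points) of 10 kb windows in FGO (x axis) and on the 2-cell maternal allele (y axis), binned by 5 points, with a logarithmic colour scale for the number of windows. Of 65311 windows, 1209 were called lower in both stages and 538 higher in both.

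Imprinted regions carry methylation set in the oocyte or the sperm through development. In FGO, 15 regions over 50% in control had a median of 94.2% in control and 94.0% in cKO, and none of the 15 passed Fisher's exact test. Examples were Kcnq1ot1, the noncoding RNA gene of its imprinted cluster (chromosome 7, 143295547 to 143297547; 95.5% and 96.1%), Airn (chromosome 17, 12740311 to 12742311; 96.4% and 95.4%) and Zrsr1 (chromosome 11, 22971005 to 22973005; 93.0% and 94.4%). Of 7 regions under 50% in FGO control, Impact fell from 10.2% to 0% (98 and 114 reads, Fisher adjusted p = 0.00557). The H19 upstream region, which is methylated in sperm, fell from 5.26% to 1.66% (Fisher adjusted p = 0.0213). Impact, Mest, Inpp5f and Grb10 are known as methylated in oocytes, but their intervals stood at 10.2%, 6.17%, 3.29% and 2.31% in FGO control. These intervals thus did not hold the methylation set in oocytes, so the fall at Impact is not a loss of an imprint. In GO, Peg3 fell from 29.97% to 10.5%, Airn from 50.4% to 28.2% and Zrsr1 from 14.4% to 1.97%, while Peg10 rose from 9.86% to 19.3% and the Rasgrf1 region from 1.49% to 37.5% (67 and 40 reads). None of 6 regions passed in MII. In 2-cell embryos, Slc38a4 was 65.0% in control (20 reads) and 100% in maternal KO (62 reads), the only region of 10 that passed. In blastocysts, Nap1l5 rose from 23.0% to 37.7%, Peg13 from 24.2% to 31.05% and Nnat from 23.0% to 30.1%, while Mcts2 fell from 39.2% to 30.3%, Slc38a4 from 31.5% to 19.2% and Rasgrf1 from 33.3% to 21.5%; the median of the 15 regions was 28.4% and 31.05%. With 500 bp to each side of the gene starts, which leaves fewer reads, 8 of these 14 calls did not recur (1 could not be tested): only Peg3 in GO and Nap1l5 and Mcts2 in blastocysts passed again, beside H19 and Rasgrf1, whose intervals were the same.

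RNA of FGO was compared to find which genes respond to loss of G9a in the oocyte. Gab1 rose from FPKM 0.697 and 0.916 in controls to 12.6 and 14.1 in cKO (log2 change 3.41, SE 0.15, limma adjusted p = 0.0192). Mt1, whose DNA was also covered more deeply in the cKO files, was listed at 0 and 0.591 in controls and rose to 68.1 and 63.2 (6.48, SE 0.40). Usp17lc, a deubiquitinase gene of the group active in 2-cell embryos, went from 0.357 and 0.227 to 15.4 and 8.15 (3.89, SE 0.34), and Reg3d, of a family of secreted lectins, from 0 and 0.0820 to 7.62 and 7.62. Gm1141 went from 0.698 and 0.478 to 38.7 and 43.2, Clec2g, a lectin gene, from 0.309 and 0.0953 to 5.96 and 5.57, and Klf12 from 0 and 0.0648 to 3.72 and 3.93. Gm4541 was listed at 0 in both controls and at 12.2 and 7.96 in cKO.

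Genes that fell in FGO included Dppa5a, a marker of pluripotent and germ cells, from FPKM 209 and 179 to 15.1 and 9.69 (log2 change -3.94, SE 0.23, limma adjusted p = 0.0243). Tex15, needed for meiotic recombination and piRNA-directed methylation in male germ cells, went from 52.4 and 55.6 to 7.45 and 7.99 (-2.73, SE 0.08), and Tacc1, a centrosomal coiled-coil gene, from 13.3 and 11.8 to 0.799 and 0.826 (-3.31, SE 0.12). Rimkla, an enzyme that joins glutamate to N-acetylaspartate, went from 97.3 and 96.6 to 15.2 and 13.9. Sox8, a transcription factor gene, fell from 29.7 and 26.4 to 7.05 and 7.07 and Tmc7, a channel-like gene, from 4.36 and 4.71 to 0.438 and 0.823. Pvrl2, which encodes the adhesion molecule nectin-2, fell from 5.22 and 5.82 to 0.673 and 1.03, Slc30a2, a zinc transporter gene, from 4.49 and 3.30 to 0.755 and 0.547, and A730008H23Rik from 22.5 and 13.7 to 0.0967 and 0.198.

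Oaz1, which encodes ornithine decarboxylase antizyme (chromosome 10, 80826656 to 80829290), and Oaz1-ps, listed within the same locus (80826696 to 80829217), are uncertain. Oaz1 had FPKM 89.6 and 98.7 in FGO controls and 4.90 and 4.95 in cKO, while Oaz1-ps was listed at 0 in both controls and at 123 and 121 in cKO; the sums were 89.6 and 98.7 against 128 and 126. In 2-cell embryos the division followed the replicate number and not the group: Oaz1-ps was listed at 0 in replicate 1 of both groups and at 208 (control) and 238 (maternal KO) in replicate 2. The copy of BC002163 on chromosome 4, listed at 0 in both controls and at 20.7 and 9.38 in cKO, is uncertain too, since the table lists this gene at more than 1 place.

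In total 114 genes rose and 59 fell among 10950 tested in FGO (limma, adjusted p under 0.05), and at an unadjusted p under 0.05 there were 1599 higher and 1195 lower. The called changes were at least 0.45 on the log2 scale, and 119 were 2-fold or more. Libraries of the groups did not overlap in 59.7% of genes, where chance gives 33.3%. Without control replicate 1 there were 8 calls, without control replicate 2 there were 6, and without cKO replicate 1 or cKO replicate 2 there were 0, with 2490 and 3008 genes at an unadjusted p under 0.05. Each of these fits takes its spread from the other group alone and assumes that the lone library varies like it, so calls are lost whichever library is left out. The log2 changes moved little for Gab1 (3.29 to 3.53) and Tex15 (-2.78 to -2.68). They moved more for Mt1 (5.92 to 7.05) and Usp17lc (3.45 to 4.33). The direction was kept for every named FGO gene, which leaving out a library could not change, since their groups did not overlap. The model over all 8 libraries called 15, and with the replicate number as a block 10 were called (5 higher and 5 lower).

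Among the lists, the kept 2-cell activation genes, which are transcribed when the embryonic genome switches on, were higher in FGO cKO, with 16 of 23 above 0. By the test over all genes 3 rose, and 11 rose when adjusted over the list alone. By limma 14 of the 23 had an unadjusted p under 0.05, against 2794 of all 10950 genes. A member under FPKM 1 in both controls, such as Usp17lc, was kept only if both cKO libraries reached 1. Members silent in both groups were not counted, so these counts and the camera test lean towards rises. The 3 that rose over all genes were Usp17lc, Obox3, a homeobox gene (log2 change 2.61), and AF067063 (1.12). Usp17le had a value of 2.96 and did not pass; Usp17l, Obox and histone genes have near-identical copies, so how reads were divided among members is uncertain. The camera adjusted p was 0.00325, and p = 0.277 with an estimated correlation. Replication-dependent histone genes were higher as well, with 54 of 62 above 0 and a median of 0.59. Of these, Hist1h2ba, a testis- and oocyte-type H2B gene (FPKM 244 and 233 against 492 and 456), and Hist4h4 (0.53) rose over all genes, and 46 rose when adjusted over the list alone (camera adjusted p = 1.21e-14, and p = 0.157 with an estimated correlation). No list held with an estimated correlation in either stage, where the smallest adjusted p was 0.900 in FGO and 0.944 in 2-cell embryos.

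Germline genes that somatic cells silence by methylation moved both ways in FGO: Wfdc15a (log2 change 1.81) and Pet2 (1.53) rose and Sycp1, of the synaptonemal complex, fell (-1.52), which was 3 of 32 over all genes and 7 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.873). Of 30 imprinted genes, Gab1 and Grb10, a growth-suppressing adaptor gene (11.9 and 12.9 against 22.9 and 22.5), rose over all genes, and 4 rose and 1 fell when adjusted over the list alone (0.873). Of 76 ribosomal protein genes, Rps16 (0.96) and Rpl10l (1.2) rose over all genes and 3 when adjusted over the list alone (0.470); these genes have many near-identical copies. C1qb, a complement gene, rose (0.69) among 4 blood and immune markers, of which 2 rose and 1 fell when adjusted over the list alone (0.873).

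Markers of granulosa and theca cells, which surround the oocyte, had a median log2 difference of 1.3 in FGO cKO over 15 members, with 0 called by limma over all genes, 1 when adjusted over the list alone and 4 at an unadjusted p under 0.05 (camera adjusted p = 0.578). The follicle hormone gene Amh had FPKM 1.31 and 2.40 in controls and 3.71 and 9.70 in cKO, and Fshr, the receptor of follicle-stimulating hormone, had a log2 difference of 1.94 that did not pass. A marker under FPKM 1 in both controls, such as Fshr, was kept only if both cKO libraries reached 1. Markers silent in both groups were not counted, so the median leans towards rises.

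In the other lists limma called 0 genes in FGO over all genes. H3K9 methylation machinery had 21 members (0 when adjusted over the list alone, 4 at an unadjusted p under 0.05; camera adjusted p = 0.873), with a log2 difference of 0.52 for the demethylase gene Kdm3a and of -0.19 for the methyltransferase gene Setdb1. DNA methylation machinery had 19 (1 higher and 2 lower when adjusted over the list alone; 4; 0.578), with -0.40 for Kdm1b, an H3K4 demethylase gene needed for oocyte methylation, and -0.33 for Dppa3, which protects the maternal genome. Oocyte-specific genes had 34 (1 and 2; 8; 0.578) and meiotic genes 30 (0; 7; 0.873; median 0.03, mean -0.01). The values were 18 (0; 4; 0.873) for maternal mRNA decay factors, 3 (0; 1; 0.873) for sperm and testis transcripts and 18 (1 and 2; 5; 0.873) for p53 targets. They were 9 (0; 1; 0.873) for inner cell mass and trophectoderm regulators, 23 (0; 2; 0.873) for heat shock and stress genes and 84 (0; 20; 0.873) for nuclear-encoded oxidative phosphorylation genes. Median and mean, or median and test, differed in sign for decay factors, sperm transcripts, p53 targets, heat shock genes and oxidative phosphorylation genes.

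In 2-cell embryos, the question was whether transcripts differ once the embryo's own genome has been activated. Tex15 stood at FPKM 66.1 and 68.2 in controls and 10.6 and 10.5 in maternal KO (log2 difference -2.61), and Ifrd1, an interferon-related regulator gene, at 39.8 and 45.7 and at 14.1 and 10.97 (-1.74). Akap8 stood at 4.88 and 16.2 in controls, against 0.142 and 0.793. Higher in maternal KO were Gm8817 (3.04 and 3.29; 27.3 and 32.0), Rab5b, an endosomal GTPase gene (0.143 and 0.118; 3.88 and 5.73), and Hist1h2bp (26.7 and 10.3; 147 and 166). The neuropeptide gene Npy and Gm9733 were listed at 0 in both controls and at 3.84 and 5.55, and 3.88 and 4.68, in maternal KO. Limma called 0 of 12083 genes in 2-cell embryos, with a smallest adjusted p of 1.00, so these genes did not pass the test. At an unadjusted p under 0.05 there were 140 higher and 110 lower, and the model over all 8 libraries called 1. Same-numbered libraries deviated together (r = 0.575), which these counts ignore; with the replicate number as a block 0 genes were called and 1530 had an unadjusted p under 0.05. Libraries of the groups did not overlap in 27.3% of genes, where chance without such a shift gives 33.3%. Libraries of 1 group differed more here than in FGO, and in simulated data with this spread 26 of 50 genes changed by 4 on the log2 scale were called.

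Replication-dependent histone genes were higher in maternal KO 2-cell embryos, with 52 of 64 above 0 (camera adjusted p = 1.18e-06, and p = 0.283 with an estimated correlation), such as Hist1h2ba (241 and 176 against 390 and 416). In this list limma called 0 genes over all genes and 0 adjusted over the list alone, with 5 at an unadjusted p under 0.05. The 2-cell activation genes had 37 of 43 members below 0 (0.0232, and p = 0.535 with an estimated correlation), such as Zscan4c, a telomere regulator of 2-cell embryos (55.1 and 34.5 against 15.8 and 7.84); without control replicate 2 the adjusted p was 0.691, and without maternal KO replicate 1 it was 0.776 and the direction was up. Inner cell mass and trophectoderm regulators had 13 of 16 above 0 (0.0232, and p = 0.0913 with an estimated correlation), such as the endoderm gene Gata6 (0.724 and 0.601 against 1.98 and 1.72), but with each library left out in turn the adjusted p ran from 0.0632 to 0.266, so that leaving out any of the control or maternal KO replicates ended this call.

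The other lists did not pass in 2-cell embryos. The camera adjusted p was 0.141 for H3K9 methylation machinery, 0.321 for DNA methylation machinery, 0.141 for oocyte-specific genes, 0.918 for meiotic genes, 0.918 for germline genes, 0.910 for decay factors (median and mean below 0, test up) and 0.621 for imprinted genes. It was 0.328 for granulosa and theca markers, 0.844 for blood markers (median and mean below 0, test up), 0.621 for sperm transcripts (median below 0, mean and test up), 0.315 for p53 targets, 0.918 for heat shock genes, 0.211 for ribosomal protein genes and 0.104 for oxidative phosphorylation genes. In each of these lists limma called 0 genes over all genes and 0 adjusted over the list alone, with at most 4 at an unadjusted p under 0.05.

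The genes called in FGO tended to differ the same way in 2-cell embryos. Gab1 stood at 0.767 and 4.01 in controls and 18.3 and 11.6 in maternal KO, Grb10 at 12.3 and 10.8 and at 22.1 and 19.7, and Tex15 as above. Of 157 such genes kept in both tables, 124 had the same sign (79.0%, against 58.2% of 9953 genes not called); among those that rose it was 76 of 104 (73.1%, against 42.8% of all genes above 0) and among those that fell 48 of 53 (90.6%, against 57.2% below 0). Across these genes the log2 changes correlated at r = 0.528 and rho = 0.558, which reflects the directions and not the sizes: r was 0.105 among the genes that rose and -0.00560 among those that fell. Genes are not independent replicates. The overlap of calls was 0, since limma called 0 genes in 2-cell embryos. The test of the change between stages called 0 of 10110 genes by limma, with 333 at an unadjusted p under 0.05 (99 higher and 234 lower in 2-cell embryos than in FGO). The smallest p belonged to Tacc1 (FGO log2 change -3.31, 2-cell difference -0.39), Usp17lc (3.89 and -0.92), Rab5b (-0.01 and 3.05), Gm1141 (5.26 and 1.26) and Ifrd1 (0.24 and -1.74), with limma adjusted p of 0.365 for the first 4 of them and 0.439 for Ifrd1.

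DNA methylation of gene bodies in FGO went with the RNA changes. The Gab1 body went from 7.15% to 57.02% in FGO, from 1.90% to 71.2% in MII and from 16.3% to 62.1% in 2-cell embryos, and was 13.2% and 16.2% in blastocysts. Gm9733 went from 45.5% to 78.9% and Pet2 from 46.4% to 81.2%. Bodies of genes that fell lost methylation at Sox8 (50.1% to 8.29%), Tmc7 (63.4% to 22.5%), Pvrl2 (76.7% to 34.1%), Slc30a2 (67.6% to 25.7%) and Tex15 (93.2% to 65.0%), while Tacc1 (94.4% and 92.6%) and Rimkla (87.9% and 89.3%), which also fell, and Gm1141 (93.8% and 92.7%), which rose, were not called.

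Of 57 genes with lower RNA and a measured body, 21 had a body called lower, where 1.36 would follow from independent lists (one-sided Fisher adjusted p = 5.56e-19); of 98 with higher RNA, 13 had a body called higher, where 0.429 would (1.13e-15). The opposite pairings held 2 genes (2.33 by chance) and 0 genes (0.250 by chance). At CG-richer gene ends, lower methylation met lower RNA in 2 genes (0.559 by chance; 0.430) and higher RNA in 1 (1.01 by chance), and higher methylation met lower RNA in 0 (0.326 by chance), while 7 genes with higher RNA were called higher in methylation (0.591 by chance; 9.85e-06), among them Klf12 (7.69% to 60.2%), Reg3d (36.1% to 86.4%), Obox3 (73.2% to 93.5%) and Gm9733 (23.2% to 58.2%). The test of bodies was chosen after seeing the data. Across 10504 genes the body difference and the log2 RNA change correlated at r = 0.316 and rho = 0.147, and across 10872 gene ends at r = 0.112 and rho = 0.0184; in 2-cell embryos the values were 0.0861 and -0.00737 (r). The median body difference was -8.56 points for genes that fell, -1.19 for genes not called and 0.437 for genes that rose. In MII and 2-cell embryos the genes that fell in FGO had median body differences of -11.4 and -13.4 points.

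**Figure D3:**
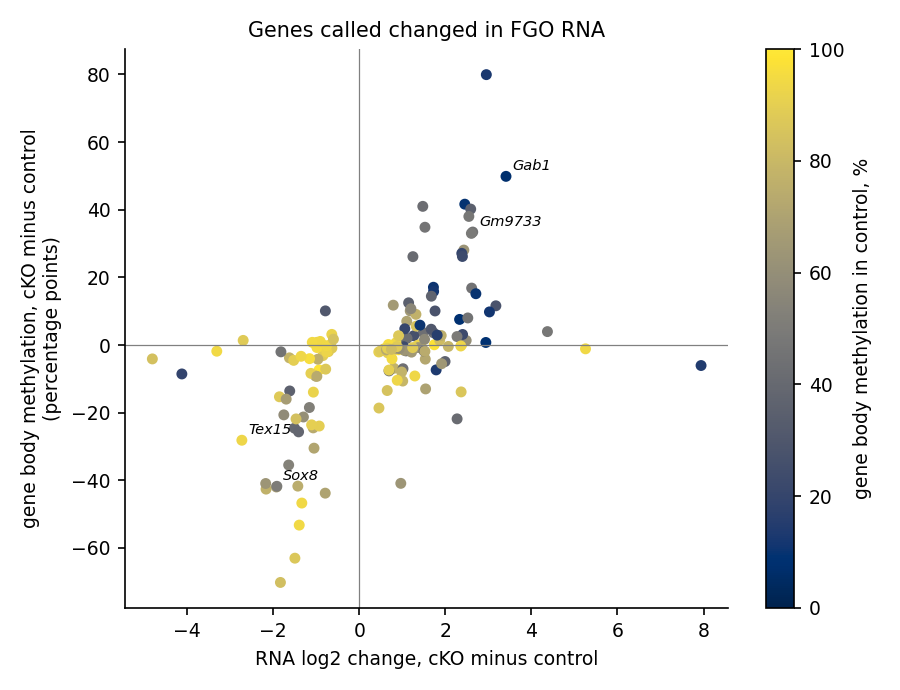
Difference of gene body methylation (percentage points, y axis) against change of RNA in FGO (log2, cKO minus control, x axis) for genes called changed in FGO RNA, coloured by body methylation in the FGO control (percent). Gab1, at 3.41 and from 7.15% to 57.02%, lies in the upper right and Sox8, at -1.92 and from 50.1% to 8.29%, in the lower left.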

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

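The tests of granulosa cell RNA, of the sign of the shift between replicates, of unfinished growth for windows called lower, of conversion for windows called in both directions and for the general fall, of pooled reads at gene ends and of a loss after the oocyte stage were chosen only after the results they bear on were seen.

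Usp17lc and Pvrl2 stood out because every knockout library lay on one side of the controls in FGO and on the opposite side in 2-cell embryos. Usp17lc rose in FGO (log2 change 3.89) and had FPKM 58.0 and 91.4 in 2-cell controls against 28.99 and 50.2 in maternal KO (-0.92; limma adjusted p of the difference between stages 0.365). Pvrl2 fell in FGO (-2.17) and had 1.58 and 2.35 against 2.77 and 2.502 in 2-cell embryos (0.36; 0.605). Neither difference between stages passed the test.

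Genes called changed in FGO RNA, such as Gab1 and Tex15, could come from strain DNA linked to a targeted Ehmt2 allele, from a library batch or from follicle cells. Of the 173 called genes, 1.16% (2 genes) lay within 20 Mb of Ehmt2, against 3.11% of all genes tested, which argues against linked DNA as the source of most calls. A batch is raised by Oaz1-ps, which split the FGO libraries by group and the 2-cell libraries by replicate number. The FGO changes correlated with the 2-cell shift between replicate numbers at rho = 0.214 (95% interval 0.0515 to 0.358), and at 0.341 among the genes that rose and -0.184 among those that fell, which decides nothing by itself. With the 2-cell knockout change rho was 0.558, and 0.167 among the genes that rose and -0.00314 among those that fell. The sign of that shift matched the FGO change in 51.6% of 157 called genes (95% interval 43.8 to 59.3), against 51.9% of genes not called. By sign, this argues against such a batch as the source of most calls. Among the genes that rose the rho leaves it open, since it was higher with the replicate shift than with the knockout change. A batch stays open for part of the calls: 4 called genes (Iqcf1, Mt1, Oaz1-ps and Obox3, named after their values were seen) shifted by over 2 on the log2 scale in both 2-cell groups. They were 2.55% of called genes, against 0.774% of genes not called, which goes with a batch for such genes.

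Follicle cells were weighed for the same genes. Granulosa markers were higher in cKO replicate 2 than in replicate 1 by 1.28 (Amh) to 2.72 (Hsd3b1) on the log2 scale, and the genes that rose had a median ratio of -0.0409, which decides nothing, since the call selects genes whose replicates agree. In 2-cell embryos, however, 73.1% of the genes that rose were higher in maternal KO (95% interval 63.8 to 80.7, against 42.8% of all genes), while the highest value of the 6 tested markers in any 2-cell library was FPKM 0.802 and the 12 granulosa and theca markers that were kept had a median difference of 0.02. This argues against RNA of such cells as the source of the rises as a set. Single genes stay open, and Fshr, a kept marker, was higher by 1.95 in 2-cell maternal KO, as it was by 1.94 in FGO, without passing in either. Bisulfite libraries also showed bodies of called genes differing the same way, 21 lower with lower RNA (1.36 by chance) and 13 higher with higher RNA (0.429 by chance). A response to the knockout stays a hypothesis found and tested on the same data.

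Windows called changed in FGO methylation, such as those of Zfp536, could come from library noise, from cKO oocytes that had not finished growing or from a difference in bisulfite conversion. Of the called windows with MII data 95.4% had the same sign in MII, from other libraries, which argues against noise. Unfinished growth leaves less methylation, so it does not give the windows called higher, of which 92.2% were higher in MII too. Of those called lower, 96.1% were lower in MII, whose oocytes have finished growing, which argues against oocytes still growing at collection as their source. It decides nothing about a deficit that stays after growth ends, since such a deficit would be present in MII too. A conversion difference lowers all windows and cannot give the 5385 windows called higher beside 7472 called lower. For the general fall, windows low in MII control had a median difference of -2.36 points in FGO, close to -2.75 in middle windows, which by itself decides nothing. Over pooled FGO reads of 4198 gene ends under 5% in MII control, the control file was higher by only 0.338 points (95% interval 0.269 to 0.402; 2.11% against 1.78%), which argues against conversion as the source of that fall. An effect of the knockout on the windows remains a hypothesis found and tested on the same data.

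In 2-cell embryos, windows under 20% in FGO control had a median difference of -8.36 points, which could come from unconverted cytosines in the control file or from paternal reads assigned to the maternal allele there. Over 7541 gene ends under 5% in FGO control the median difference between the files was 0, which decides nothing because most such ends had no methylated read, and over their pooled reads the control file was higher by 0.733 points (2.12% against 1.38%), too little for unconverted cytosines to account for the windows. Paternal reads remain a candidate explanation: the regions upstream of H19 and Meg3, methylated in sperm, were higher in the 2-cell control file by 11.1 points (15 of 135 against 0 of 82 reads). With Rasgrf1 added, which the 2-cell value lacks, these regions differed in oocytes, which hold no paternal DNA, from 6.79% to 3.68% in FGO and from 1.41% to 6.98% in GO. Rasgrf1 alone went from 1.49% to 37.5% in GO (67 and 40 reads). H19 and Meg3 went from 0.442% to 1.70% and from 2.44% to 9.15% in GO, and from 5.26% to 1.66% and from 6.83% to 4.36% in FGO. The 2-cell value therefore does not settle it. Slc38a4, methylated in oocytes, was 65.0% in the 2-cell control file against 100% in maternal KO. The knockout files averaged 6.73% over these windows in FGO and 5.52% in 2-cell embryos, a mean difference of -1.21 points, whereas the control files went from 8.58% to 13.97% (with 6.30% in MII, over fewer windows). This decides nothing about a loss in the knockout after the oocyte stage. Each stage was read at its own shared positions, and the 2-cell files hold only reads assigned to the maternal allele. A shift common to both 2-cell files, as large as the rise in the controls, would hide such a loss. A gain on the maternal allele of controls was not tested, and it stays open beside such a loss and paternal reads.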

How the results depend on the processing

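Positions over 200 reads, all positions of each file for windows and the thresholds of the control background were chosen after seeing the data; the other alternatives were planned. In 311 of 311 settings of 21 named FGO genes and 159 of 159 of 11 named 2-cell genes the direction was kept. The groups of these genes did not overlap, so another pseudocount, a replicate block or leaving out a library could not reverse it. Under all settings 481 values kept their direction and call (or, with no test, lay within the interval or 1.5 times the count), though sizes could differ, 112 lost their call, 1 gained one, 68 moved and 2 reversed; the cause was not tested unless given. FGO RNA calls numbered 99 without a filter, 112 at FPKM of at least 5, 300 without trend, 15 with all 8 libraries in 1 model, 1100 at an adjusted p of 0.1 and 0 to 8 with 1 library left out, where fewer samples remain. The 2-cell count was 1 with all 8 libraries. With the replicate number as a block, FGO calls numbered 10 and genes differing between stages 1, and 2-cell genes at an unadjusted p under 0.05 numbered 1530 in place of 250; same-numbered libraries deviated together at r = 0.145 in FGO and 0.575 in 2-cell embryos, but 2 pairs do not show that the numbers pair the samples. With an estimated correlation 0 lists passed in FGO and 0 in 2-cell embryos, where leaving out 1 library gave 1 to 6 lists, and the 2-cell activation genes had adjusted p from 1.43e-05 (without maternal KO replicate 2) to 0.776 (without replicate 1, direction up), with 0.691 without control replicate 2.

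The GO global difference was -0.344 at positions with 3 reads or more, -0.404 at 5 or more and -0.114 over all positions of each file. The FGO one was -2.09 as a mean of positions. MII gave -2.22 at 5 reads or more, -1.48 as a mean of positions, -1.86 over all positions and -2.56 without positions over 200 reads. The 2-cell one was -0.596 at 3 reads or more, reversed to 0.271 at 5 or more and was -5.72 as a mean of positions and -6.20 without positions over 200 reads. Blastocysts gave -0.683 at 5 reads or more. Windows of 2 kb gave 8711 calls in GO, 62429 in FGO, 15474 in 2-cell embryos and 10155 in blastocysts. A threshold of 10 points gave 7450, 41224, 20605 and 7819, and 30 points gave 208, 4614, 2838 and 17, with 386 in MII. At least 100 reads per window gave 610 (GO), 58 (MII), 2311 (2-cell) and 193 (blastocyst), and positions with at least 3 reads gave 38 (MII), 1831 (2-cell) and 722 (blastocyst); all positions of each file gave 9769 in MII. The control background was 9549 windows at 10 points and 1016 at 30. Gene ends at 10 and 30 points numbered 325 and 30 in GO, 1320 and 306 in FGO and 487 and 18 in blastocysts, with 288 at 30 points in 2-cell embryos. Gene bodies numbered 663 and 14 in GO, 2063 and 271 in FGO, 1301 and 405 in MII, 4093 and 555 in 2-cell embryos and 326 and 6 in blastocysts. Imprinted regions of 500 bp to each side gave 7 calls, against 14. Depth limits MII and 2-cell embryos most, whose files shared 1740221 and 3539600 autosomal positions, against 28014627 in FGO.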

Other observations

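The tests of gene body methylation and of Mt1 DNA copies were chosen only after the results were seen.

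Chromosome X was lower in the knockout files in the same later stages as the autosomes: without positions over 200 reads it stood at 44.3% and 40.5% in FGO, 49.5% and 44.4% in MII and 40.4% and 31.5% on the 2-cell maternal allele, with a difference of -0.133 points in blastocysts (autosomes -0.354). In GO it went the other way, by 0.431 points against -0.152 on the autosomes. The 21 genes with lower RNA and a body called lower in FGO included Irf8, an interferon regulatory factor gene, Efnb1, an ephrin gene, Chst11, a chondroitin sulfotransferase gene, and Mtap, of the methionine salvage pathway. The 13 with higher RNA and a body called higher included Ephb1, an ephrin receptor gene, Brsk1, a kinase gene, Tlr8, a sensor of RNA, and Stc2, which encodes a secreted glycoprotein. These genes were named after their values were seen.

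Gene body methylation may follow transcription during oocyte growth, which would raise body methylation in genes that rose. The median FGO body difference of the genes that rose was 0.437 points, with quartiles at -1.80 and 9.60, which decides nothing, since members went both ways and many bodies were highly methylated already. Of 98 such genes, 53 lay above 0, against 2965 of 10349 genes not called, whose median was -1.19; 44 had a control body under 50%, and 12 of these gained at least 20 points, among them Gab1 (7.15% to 57.02%). Bodies of genes that fell had a median difference per gene of -8.56 points. Their median levels, each taken by itself, were 84.6% in control and 65.5% in cKO. These values go with the hypothesis, which was found from them and stays open.

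The higher Mt1 RNA in FGO cKO may come from extra copies of Mt1 DNA in the knockout animals, for example within a transgene. The stretch that holds Mt1 had a scaled ratio of knockout to control reads of 6.40 in MII, the lowest of GO, MII and blastocysts, while its flanks stayed at 1.06 or below. Such copies would need these values. The stretch was singled out because it passed 4-fold in these same stages, so its ratios there could not fail and add no support. In FGO the RNA stood at FPKM 0 and 0.591 in controls against 68.1 and 63.2 in cKO, whereas in 2-cell embryos Mt1 stood at 14.7 and 98.9 against 19.7 and 92.5. A stretch that ends 105 bp before Zp3 had a scaled ratio of 20.2 in FGO, where Zp3 RNA stood at FPKM 1056 and 1010 in controls and 1058 and 1031 in cKO. A transgene with a Zp3 promoter and a metallothionein segment could give both stretches, but the labels name none and no sequence was read, so this stays a hypothesis.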
